A study of Danio rerio with 12 samples.

How the data were processed

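Gene expression was measured in 12 pools of whole zebrafish larvae, 3 at each of 4 doses of coal dust extract, with 1 one-colour Agilent array per pool. The spot intensities are background-subtracted and spatially detrended fluorescence that the authors obtained with Agilent Feature Extraction 11.5 (per the labels), with no normalization between arrays stated. Raw median intensities of spot and local background, and flags for spots well above background, saturated or not uniform, are in the same files per the file headers. The deposited table of values per array holds intensities within 0.5 percent of the processed signal. The authors' deposited tables give probes per dose with a signed fold change, a score that is the ratio to 0 ppm and is negative where the dose is lower, and with its log2; the test behind them is not stated in the labels. The sample sheet gives no total per array other than signal, so depth is described by signal over background.

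Spots with an outlier flag were set aside and the others of a probe averaged, probes left without a value on some array (7495) were left out, and log2 processed signals were shifted to the 75th percentile of each array. Of 120796 probes measured on all arrays, the 89578 that were well above background on every array of at least 1 dose group were kept. Probes were matched to genes through the transcript accession of the array's annotation and a RefSeq gene table, which named 13547 genes for 39952 of 128291 probes. The other 88339 probes were not used in tests of genes. Of the kept probes 36042 were matched, and each of 12998 genes was represented by the probe with the highest mean; 9692 of these genes had 2 or more kept probes. Gene names come from that table, and no coordinates are given, since only neighbour relations were used.

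Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the reading package data.table (version 1.17.8). All 12 arrays and 4 group means were in 1 model without a block, and p-values were adjusted by Benjamini and Hochberg over all genes with a threshold of 0.05. Each of 3 doses was compared with 0 ppm and the doses with each other, with an F-test over the 3 doses and a slope on log10(dose in ppm + 1). The p-values measure the spread between pooled samples of 50 larvae. The 42 gene lists of at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists at each dose, and members were also adjusted over the list alone. The test, the filters, the lists, the rule for naming genes and the alternatives were fixed before the data were examined, apart from those named as chosen later.

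The genes named were the 12 largest rises and 12 largest falls at 100 ppm among genes past the test with 1 sign in the 3 same-numbered pairs, without provisional names. At 10 and 1 ppm, where no gene passed, they were the 5 with the lowest p. In each list up to 4 members past the test were named per dose by size of change, or up to 2 with the lowest p where none passed. A single list member that this rule names at 1 ppm is not reported here. cyp1a, cyp1b1, cyp1c1, ahrra, hmox1a, mt2 and hsp70l were always named, as were the 5 steepest rises and 5 steepest falls of the trend. The genes that differed between doses, retinoic acid genes, progenitor genes and probes without a matched gene were chosen after their values were seen. For a gene not well above background on any array of a group, the change is given as at least N-fold, with the lowest level of a probe well above background on that array in place of a lower measured one.

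Whether equal replicate numbers belong together was checked by correlating deviations from the dose means. The median r was 0.30 between arrays of the same number and -0.17 between others, and the lowest, between 100 and 0 ppm of number 3, was 0.05. Since a replicate number is also a slide, the block for replicate and that for slide are the same model. The correlation of changes between doses was compared with 100 simulations of unchanged groups against a shared, simulated 0 ppm group.

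The alternatives were normexp background correction with an offset of 50 on the median signal (the mean signal is not a column of these files), quantile normalization, scaling by the median of probes well above background, the deposited table of values, no filter and a stricter filter (78178 probes). Others were the mean of a gene's probes, every kept probe, a replicate or slide block, only the groups compared, eBayes with trend and robust, array weights, an unadjusted p with a change of 1.5-fold, an adjusted p below 0.1, the rank of the dose, camera with an estimated correlation, fry, and leaving out each array and each replicate number. Leaving out 100 ppm replicate 3 together with a replicate block was chosen after seeing the data.

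The model was tested on simulated data with the spread of these arrays, the same for all doses of a gene. A wider spread at 100 ppm was not simulated. Of 50 genes planted at each size, 14 were recovered at a log2 change of 0.5, 39 at 1, 49 at 1.5 and 50 at 2, with 7 of 12758 unchanged genes called. With the spread found without 100 ppm replicate 3, 31, 49, 50 and 50 were recovered. A planted list was called and 0 of 41 others were. The simulated genes were drawn independently and without a slide effect. In the data the estimated correlation was 0.34 among photoreceptor genes and 0.64 among exocrine pancreas genes. The simulation is therefore no check of false calls for lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.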

Results

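Expression was measured in whole wild-type AB zebrafish larvae at 72 hours post fertilization (hpf). Embryos had been kept from about 1 hpf in water with an aqueous extract of coal dust at 0, 1, 10 or 100 ppm. Each sample was a pool of 50 larvae, and each dose had 3 samples that the labels call biological replicates. The 12 RNA samples were labelled with Cy3 and each was hybridised to 1 Agilent array holding 176026 non-control spots for 128291 probes. All 4 doses of a given replicate number lay on the same slide, so the 3 replicate numbers are also the 3 slides, and the doses always took the same order of positions on it. Dose and position on the slide therefore cannot be told apart. The background-corrected signal had a median between 168 and 225 on 11 arrays and of 99.1 on the array of 100 ppm replicate 3. Between 76.0% and 81.0% of spots were well above background on those 11 arrays, and 70.6% were on 100 ppm replicate 3. No spot was saturated. The number of arrays, 3 per dose, limits the precision of every value given here.

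After scaling, the first principal component held 58.8% of the variance and separated 100 ppm replicate 3, with a score of 74.8, from the other 11 arrays, with scores between -14.9 and 8.75. Its median correlation with the other arrays was 0.976, against 0.994 to 0.997 for the rest. The second component held 11.4% of the variance and the third held 8.09%. Because this array stands apart, values per slide are given beside the lists that shifted at 100 ppm and beside several other lists. After filtering, 12998 genes were tested, each by its brightest probe. Values are log2 signals relative to the array's 75th percentile, and differences are means of 3 arrays minus means of 3 arrays ± SE.

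**Figure D1:**
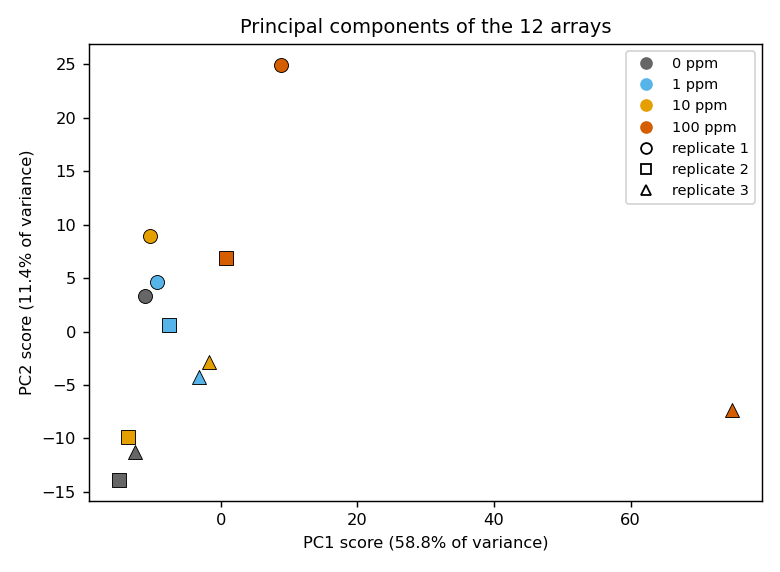
Scores of the 12 arrays on the first and second principal components of the log2 values of 12998 genes, coloured by dose with 1 symbol per replicate number; the axes give the share of variance. The array of 100 ppm replicate 3 lies at 74.8 on the first component and all other arrays lie between -14.9 and 8.75.

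The comparison of each dose with 0 ppm asks which transcripts of the whole larva differ after exposure to coal dust extract through embryonic development. At 100 ppm the clearest change was in smtlb, which encodes the pituitary hormone somatolactin beta: its level went from -1.90 ± 0.09 (SD, n = 3) at 0 ppm to -3.87 ± 0.22 (SD, n = 3) at 100 ppm and so fell by 1.97 on the log2 scale, 3.93-fold (adjusted p = 0.000102 by limma). It fell on each slide, by 1.96, 2.12 and 1.84 on the log2 scale. The largest rise was that of fabp4b, a fatty acid binding protein gene, from 1.36 ± 0.09 (SD, n = 3) to 3.06 ± 0.36 (SD, n = 3), a difference of 1.71 ± 0.16 or 3.26-fold (adjusted p = 0.00246). Among the other genes that rose were the somite transcription factors tbx16l (1.02 ± 0.21) and tcf15 (0.98 ± 0.21) and mitfa, the transcription factor that specifies melanophores (0.98 ± 0.13).

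The other large rises were those of gbp1, an interferon-induced GTPase (1.29 ± 0.31), and of oc90, a matrix protein of the otoliths (1.16 ± 0.18). Those of polr2i, a subunit of RNA polymerase II (2.14-fold), irf1a, an interferon regulatory factor (1.01 ± 0.26), and msnb, a moesin that ties the membrane to actin (0.99 ± 0.14), followed. So did those of pnp5a, a purine nucleoside phosphorylase (0.96 ± 0.26), pth1a, which encodes parathyroid hormone (0.95 ± 0.18), and the tetraspanin gene cd151l (0.95 ± 0.22). Of their probes kept in the analysis, 3 of 4 for oc90 and 5 of 6 for pnp5a had the sign given.

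Among the 12 largest falls were those of sv2ba, a synaptic vesicle glycoprotein (-1.68 ± 0.41), syt10, a synaptotagmin (-1.59 ± 0.43), and gjd2b, a connexin of electrical synapses (-1.47 ± 0.25). kctd16b, an auxiliary subunit of GABA-B receptors, was well above background on all arrays at 0 ppm and on no array at 100 ppm, and was at least 2.08-fold lower (adjusted p = 0.0172). cacng7a, a calcium channel and glutamate receptor subunit, was likewise not well above background on any array at 100 ppm and was at least 2.76-fold lower (adjusted p = 0.0323). The receptor tyrosine kinase gene tyro3 was well above background on 1 of 3 arrays at 100 ppm (-1.73 ± 0.47). The remaining falls of the 12 largest were those of abcc5, an ABC transporter (-1.81 ± 0.32), mapk3, which encodes ERK1 (-1.68 ± 0.34), and mef2d, a transcription factor of muscle and neurons (-1.53 ± 0.25). Those of sim1a, a transcription factor of the hypothalamus (-1.50 ± 0.30), and itln2, a lectin of the intelectin family (-1.49 ± 0.21), complete the 12. For mapk3 and sim1a, only 1 of 2 probes had the sign given. Many of these falls were deepest on the slide of 100 ppm replicate 3: sv2ba differed by -0.79, -1.18 and -3.07 on the 3 slides, and mapk3 by -0.88, -1.25 and -2.90.

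**Figure D2:**
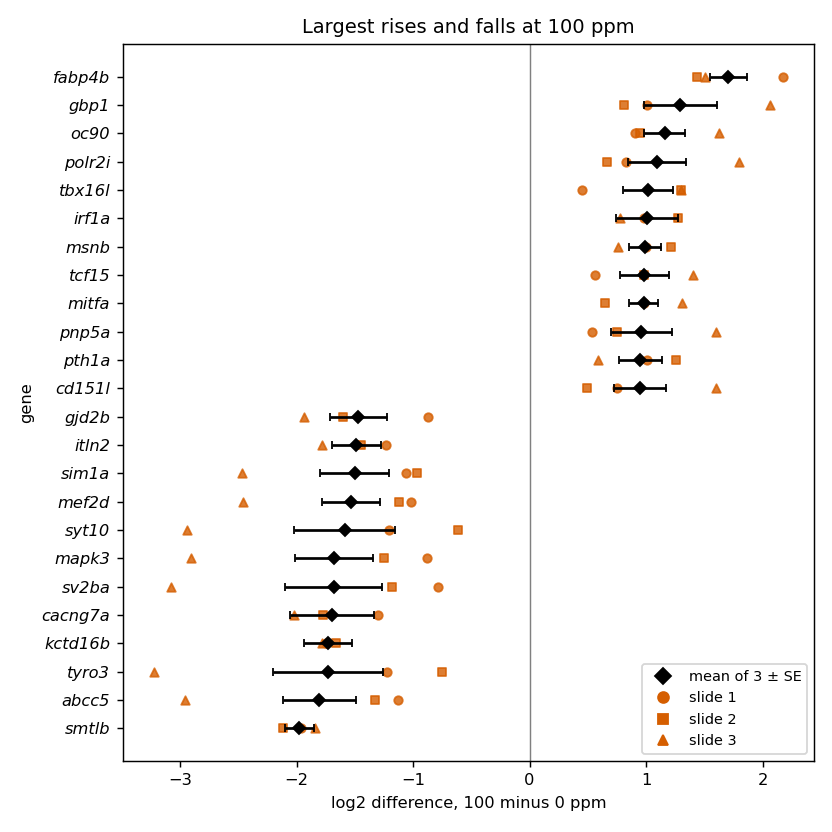
Log2 difference between 100 and 0 ppm of the 12 largest rises and 12 largest falls. Black diamonds are differences between means of 3 arrays per dose. Their bars are limma's SE from the spread shared by all doses, and orange symbols are the differences within each slide. smtlb lies at -1.96, -2.12 and -1.84 on the 3 slides, while sv2ba and mapk3 reach -3.07 and -2.90 on slide 3. kctd16b and cacng7a were not well above background at 100 ppm, so their plotted values are measured signals and not bounds.

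In all, 988 of 12998 genes passed limma's test at 100 ppm at a Benjamini-Hochberg adjusted p below 0.05, of which 634 were higher and 354 lower. Each of them differed in the same direction on all 3 slides, as did 54.2% of all genes. The test that picked them used these same arrays and favours changes of 1 sign, so this is not separate support. Their median size was 0.55 on the log2 scale, and 95 differed by at least 2-fold. The median difference of all genes at 100 ppm was 0.11, so medians of gene lists are given relative to it where stated. Medians per slide are plain differences within a slide, not relative to all genes, and carry any shift of all genes there. Counts of list members higher or lower are against 0, not against that median. A list near that median can therefore hold more genes above 0 than below. Scaling each array by the median of probes well above background moved the share of higher calls from 64.2% to 77.8% (1386 higher and 396 lower). The balance turned with the mean of a gene's probes (301 higher and 411 lower) and with an unadjusted p below 0.05 and a change of 1.5-fold (424 higher and 857 lower). With slide as a block, 2056 genes passed (1306 higher and 750 lower), the 988 among them. The count was 2 without each single 0 ppm array in turn and 33, 49 and 65 without 1 ppm replicate 1, 2 and 3. It was 60, 380 and 393 without 10 ppm replicate 1, 2 and 3, and 1249, 4251 and 1698 without 100 ppm replicate 1, 2 and 3. More genes were lower than higher without 1 ppm replicate 1 (13 higher and 20 lower), 2 (18 and 31) or 3 (23 and 42), without 10 ppm replicate 1 (20 and 40) and with every kept probe (1 and 2). With only the 0 and 100 ppm arrays in the fit, 0 genes passed. The main fit gives all doses 1 spread per gene, though the 100 ppm arrays strayed further from the others of their dose. The SD of these deviations between genes was 0.26, 0.30 and 0.45 at 100 ppm and 0.07 to 0.15 on the other arrays. The 988 calls depend on that shared spread. At an unadjusted p below 0.05, 4782 genes differed, against 649.9 that chance alone would give if the shared spread held at 100 ppm. That spread can be too narrow for this comparison and its p-values too small, so the excess over 649.9 can be overstated.

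Genes of the retina and of neurons were lower at 100 ppm. Of 47 photoreceptor genes 44 were lower, with a median of -0.53 relative to all genes, and 5 fell by the gene test (9 adjusted over the list alone). They included saga, a rod arrestin (-1.20 ± 0.23), nrl, a rod transcription factor (-1.02 ± 0.21), opn1sw1, the ultraviolet cone opsin (-0.92 ± 0.24), and gucy2d, a retinal guanylate cyclase (-0.85 ± 0.21). The list passed camera with an adjusted p of 4.1e-11, but not with an estimated correlation between its genes (adjusted p = 0.563 with an estimated correlation) or with fry. Its plain median was -0.24, -0.75 and -0.17 on slides 1, 2 and 3. Without 100 ppm replicate 2 its median relative to all genes was -0.31. Of 52 neuronal genes 39 were lower and 15 fell (16 adjusted over the list alone). They included cplx4a, a complexin (-1.20 ± 0.21), slc17a6b, the vesicular glutamate transporter (-1.12 ± 0.21), slc32a1, the vesicular GABA transporter (-1.10 ± 0.16), and vamp2, a synaptobrevin (-1.08 ± 0.27). The neuron list fell at an adjusted p of 3.7e-08 and also with an estimated correlation (adjusted p = 0.0291 with an estimated correlation). It was the only list of the 42 whose shift held that way. Its median was -0.23, -0.18 and -0.33 on the 3 slides, lowest on that of 100 ppm replicate 3.

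Glial genes did not shift as a list by camera (adjusted p = 0.958; adjusted p = 0.0385 with fry), yet 4 of 23 passed the gene test (7 adjusted over the list alone). The glial water channel gene aqp4 fell (-1.08 ± 0.29), while fabp7b (0.70 ± 0.11), sox2 (0.53 ± 0.14) and her4.1 (0.49 ± 0.10), genes of neural progenitors and radial glia, rose. In the lens list (adjusted p = 0.351), 2 of 59 genes rose, the crystallin genes crygm7 (0.72 ± 0.16), which was well above background on 2 of 3 arrays at 0 ppm, and crygm4 (0.63 ± 0.13). In the list of hair cells and ear (adjusted p = 0.958), oc90 was the only one of 17 to pass over all genes, and 6 passed adjusted over the list alone, 5 higher and 1 lower. Crystallins and opsins belong to families of similar sequence, so single members are uncertain.

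Digestive genes were lower at 100 ppm as well. In the exocrine pancreas list, 16 of 18 zymogen genes were lower with a median of -0.95 relative to all genes, and 2 fell (14 passed adjusted over the list alone, 13 lower and 1 higher). These were cpa4, a carboxypeptidase (-0.93 ± 0.19), and prss59.2, a trypsin-like protease (-0.90 ± 0.23). The list's adjusted p was 3.6e-06 (adjusted p = 0.683 with an estimated correlation), and it did not pass fry. Its plain median was -0.32, -1.50 and -0.50 on the 3 slides. Without 100 ppm replicate 2 its median relative to all genes was -0.57. In the intestine list (adjusted p = 0.0157; adjusted p = 0.721 with an estimated correlation), 16 of 25 genes were lower, and the median was 0.03, -0.41 and -0.24 on the 3 slides. The peptide transporter gene slc15a1b fell (-1.15 ± 0.24) and the fatty acid binding protein gene fabp1b.1 rose (0.54 ± 0.11), with 5 passing adjusted over the list alone. The liver list did not shift (adjusted p = 0.209), and none of its 38 genes passed; the lowest p belonged to serpina7 (-0.65) and apoa4b.1 (0.30).

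The series' title names connective tissue and blood for these same samples, so the direction of the lists on those themes is not independent evidence. Collagen genes were lower, 14 of 18, with a median of -0.28 relative to all genes. Not set against all genes, it was -0.21, -0.20 and -0.19 on the 3 slides. The list's adjusted p was 0.00448 (adjusted p = 0.191 with an estimated correlation), and no single collagen passed, also adjusted over the list alone. The lowest p belonged to col2a1a (-0.50; adjusted p = 0.0579) and col5a3a (-0.37; adjusted p = 0.0585). Of 35 genes of cartilage and bone 22 were lower (adjusted p = 0.0137; adjusted p = 0.191 with an estimated correlation), with medians of 0.01, -0.11 and -0.30 on the 3 slides. Among them phospho1, a phosphatase of bone mineralisation (-0.89 ± 0.22), and hapln1a, a link protein of the hyaluronan matrix (-0.60 ± 0.12), fell. The list of other matrix genes did not shift (adjusted p = 0.479; its median was above 0 while the test pointed lower). Within it hapln1a and the lysyl oxidase genes loxl1 (-1.01 ± 0.27) and loxl3a (-0.68 ± 0.15), which crosslink collagen and elastin, fell, and 2 of 50 passed adjusted over the list alone. serpinh1b, the collagen chaperone HSP47, rose (0.84 ± 0.13).

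Genes of blood cells did not shift as lists at 100 ppm by camera. In the erythroid list (adjusted p = 0.291, adjusted p = 0.0244 with fry), 28 of 36 genes were higher than 0, but its median relative to all genes was only 0.04. Its plain medians were 0.07, 0.21 and 0.28 on the 3 slides. Of its genes 2 rose, also adjusted over the list alone: alas2, the erythroid enzyme that begins haem synthesis (0.69 ± 0.13), and blvrb, a biliverdin reductase (0.42 ± 0.09). In the myeloid list (adjusted p = 0.655), 25 of 32 were higher than 0, with a median of 0.04 relative to all genes. Of these 2 rose, also adjusted over the list alone: the macrophage gene mpeg1.1 (0.61 ± 0.15) and rac2, a GTPase of leukocytes (0.45 ± 0.08). No gene passed in the lists of thrombocytes and coagulation (adjusted p = 0.797), blood vessels (adjusted p = 0.773) or complement and acute phase (adjusted p = 0.496). Their lowest p belonged to fga (0.33) and plg (0.37), to egfl7 (0.55) and cldn5b (0.57), and to c3a.2 (-0.45) and c8a (0.22). In the interferon list (adjusted p = 0.678), gbp1, irf1a and mxe (0.41 ± 0.11) rose. In the inflammation list (adjusted p = 0.958), both genes for inducible cyclooxygenase rose, ptgs2a (0.50 ± 0.08) and ptgs2b (0.50 ± 0.12), and 7 of 25 passed adjusted over the list alone.

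Genes of cell division and of protein turnover were higher at 100 ppm. Of 42 cell cycle genes 40 were higher, with a median of 0.23 relative to all genes, and 12 rose (25 adjusted over the list alone). They included birc5a, which encodes survivin (0.65 ± 0.13), the histone mRNA binding protein gene slbp (0.61 ± 0.14), the dUTPase gene dut (0.60 ± 0.13) and ccna2, which encodes cyclin A2 (0.54 ± 0.10). The list's adjusted p was 1.9e-05 (adjusted p = 0.607 with an estimated correlation), and its plain median was 0.25, 0.23 and 0.38 on the 3 slides. Of 36 proteasome genes 35 were higher and 5 rose (11 adjusted over the list alone), among them psmc1a (0.43 ± 0.11), psmb1 (0.41 ± 0.11), psme3 (0.38 ± 0.09) and psmd4a (0.30 ± 0.08). That list's adjusted p was 0.000202 (adjusted p = 0.683 with an estimated correlation). Of 25 genes of the unfolded protein response 23 were higher and 3 rose (7 adjusted over the list alone): sdf2l1 (0.64 ± 0.11), trib3 (0.54 ± 0.12) and calr3b (0.45 ± 0.10). That list's adjusted p was 0.00577 (adjusted p = 0.607 with an estimated correlation). The plain medians of both lists, which carry any shift of all genes on a slide, were highest on that of 100 ppm replicate 3. Proteasome genes stood at 0.20, 0.21 and 0.43, and the unfolded protein response at 0.21, 0.19 and 0.51.

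Genes of the circadian clock were lower, with a median of -0.30 relative to all genes (adjusted p = 0.000224; adjusted p = 0.191 with an estimated correlation). Of 32 genes, 3 fell (4 adjusted over the list alone): the clock output transcription factors dbpa (-1.32 ± 0.31) and hlfa (-0.78 ± 0.18) and the core clock gene bmal1b (-0.76 ± 0.10). The list's median was -0.19, -0.12 and -0.34 on the 3 slides.

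Known markers of exposure did not pass at 100 ppm. The cytochrome P450 genes induced through the aryl hydrocarbon receptor differed by 0.39 ± 0.15 for cyp1a, 0.43 ± 0.20 for cyp1b1 and 0.41 ± 0.14 for cyp1c1 (adjusted p = 0.0976, 0.154 and 0.0739). With slide as a block cyp1c1 passed (adjusted p = 0.0494), and with the mean of its probes cyp1b1 differed by -0.31. The stress genes hmox1a (0.50 ± 0.25), hsp70l (0.43 ± 0.16) and mt2 (-0.25 ± 0.11) did not pass either. The receptor's repressor ahrra differed by -0.03 ± 0.10, a sign that quantile normalization, median scaling and the mean of probes each turned. Its relative ahrrb fell (-0.45 ± 0.12) and was the only gene of the receptor's list to pass (adjusted p of the list 0.958; 2 of 14 adjusted over the list alone). The list of other enzymes of drug metabolism was lower (adjusted p = 0.0336; adjusted p = 0.721 with an estimated correlation), and of its 21 genes nr1i2, the pregnane X receptor, fell (-0.61 ± 0.12). That list's median was 0.03, -0.16 and -0.10 on the 3 slides. Among 23 antioxidant genes (adjusted p = 0.825), abcc2, a conjugate export pump, fell (-0.56 ± 0.13), and txnrd3 (0.50 ± 0.13) and prdx1 (0.46 ± 0.11) rose. In the heat shock list (adjusted p = 0.351; adjusted p = 0.0381 with fry), serpinh1b was the only gene to pass, and the median was 0.20, 0.09 and 0.41 on the 3 slides. None passed in the metal list (adjusted p = 0.875), where hsp70.3 (0.38) and slc39a10 (0.27) had the lowest p. In the list of p53 targets and DNA damage (adjusted p = 0.209), casp3b (0.62 ± 0.17) and gadd45bb (0.36 ± 0.09) rose, tp53inp1 (-0.55 ± 0.14) and xpc (-0.45 ± 0.09) fell, and 8 of 24 passed adjusted over the list alone. Only 1 of 2 probes of xpc had that sign, and the list's median was 0.17, 0.07 and 0.58 on the 3 slides.

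Muscle, skin, ion transport, pigment, hormone and metabolic genes did not shift as lists by camera, though single members passed. In skeletal muscle (adjusted p = 0.886) 4 genes rose and 1 fell. Among them were the rises of atp2a1l (0.64 ± 0.17), tnnt2d (0.60 ± 0.12) and unc45b (0.46 ± 0.09) and the fall of tnni2a.1 (-0.60 ± 0.15). With the mean of all their probes atp2a1l and unc45b differed by -0.05 and -0.02. Cardiac muscle (adjusted p = 0.446; adjusted p = 0.0381 with fry) had the rises of cmlc1 (0.42 ± 0.10), hand2 (0.40 ± 0.11) and tnni1c (0.34 ± 0.09). Among myogenic regulators (adjusted p = 0.295) only mef2d passed. Of the genes of the skin list (adjusted p = 0.951) and of the glucocorticoid list (adjusted p = 0.805), the annexin gene anxa1c rose (0.74 ± 0.14) and anxa1b fell (-0.71 ± 0.11). In ionocytes and kidney (adjusted p = 0.414), the epithelial calcium channel gene trpv6 (-0.76 ± 0.13) and the sodium pump gene atp1a1a.3 (-0.44 ± 0.11) fell. A dimmer probe of trpv6 fell by 1.54 ± 0.14 and was 1 of 5 to pass in the test of every kept probe (adjusted p = 0.0195). In the pigment list (adjusted p = 0.254; adjusted p = 0.0274 with fry), mitfa, trpm1b (0.72 ± 0.11) and the melanin enzyme gene tyrp1b (0.64 ± 0.14) rose. Among hormone genes (adjusted p = 0.289), smtlb fell, and cyp17a1, of steroid synthesis (0.66 ± 0.16), and dio2, the deiodinase that activates thyroid hormone (0.58 ± 0.13), rose. In lipid metabolism (adjusted p = 0.209), the desaturase gene scdb (-0.72 ± 0.15) and acox3 (-0.49 ± 0.10) fell and acadl (0.38 ± 0.10) rose. Hypoxia and glycolysis (adjusted p = 0.880) had the rise of the myoglobin gene mb (0.78 ± 0.17), and oxidative phosphorylation (adjusted p = 0.880) that of ndufa5 (0.42 ± 0.11), which did not pass adjusted over the list alone. No gene passed in sterol synthesis (adjusted p = 0.414; insig1 -0.73 and sc5d -0.59), in yolk and egg transcripts (adjusted p = 0.928; he1.1 1.19 and mttp -0.80), or among 74 ribosomal protein genes (adjusted p = 0.351; rpl29 0.28 and rps10 -0.26). Adjusted over the list alone, 9 of 19 cardiac, 7 of 17 myogenic and 6 of 56 skeletal muscle genes passed, as did 3 of 16 glucocorticoid, 3 of 28 ionocyte and kidney and 4 of 23 pigment genes. Medians on the 3 slides were 0.21, 0.18 and 0.48 for cardiac muscle, 0.05, -0.05 and 0.29 for hypoxia and glycolysis and -0.19, -0.04 and 0.31 for ribosomal protein genes.

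In sum of the list test, 11 of 42 lists shifted at 100 ppm, 3 higher and 8 lower, and the same 11 did so with slide as a block. With an estimated correlation 1 of the 11 shifted, and another split of the same 6 arrays gave 17 lists. With fry, which asks whether a list's genes move one way on balance without setting them against other genes, 11 lists also passed, 6 of them among those of camera. The 5 others of camera did not: photoreceptor (adjusted p = 0.0779), exocrine pancreas (adjusted p = 0.127), intestine (adjusted p = 0.376), cartilage and bone (adjusted p = 0.0842) and drug metabolism (adjusted p = 0.352). The 5 that passed fry alone, all with a median above 0, were the erythroid, cardiac muscle, pigment, heat shock and glial lists. Relative to all genes their medians were 0.04, 0.19, 0.20, 0.12 and 0.003, so a shift of all genes can enter these calls.

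**Figure D3:**
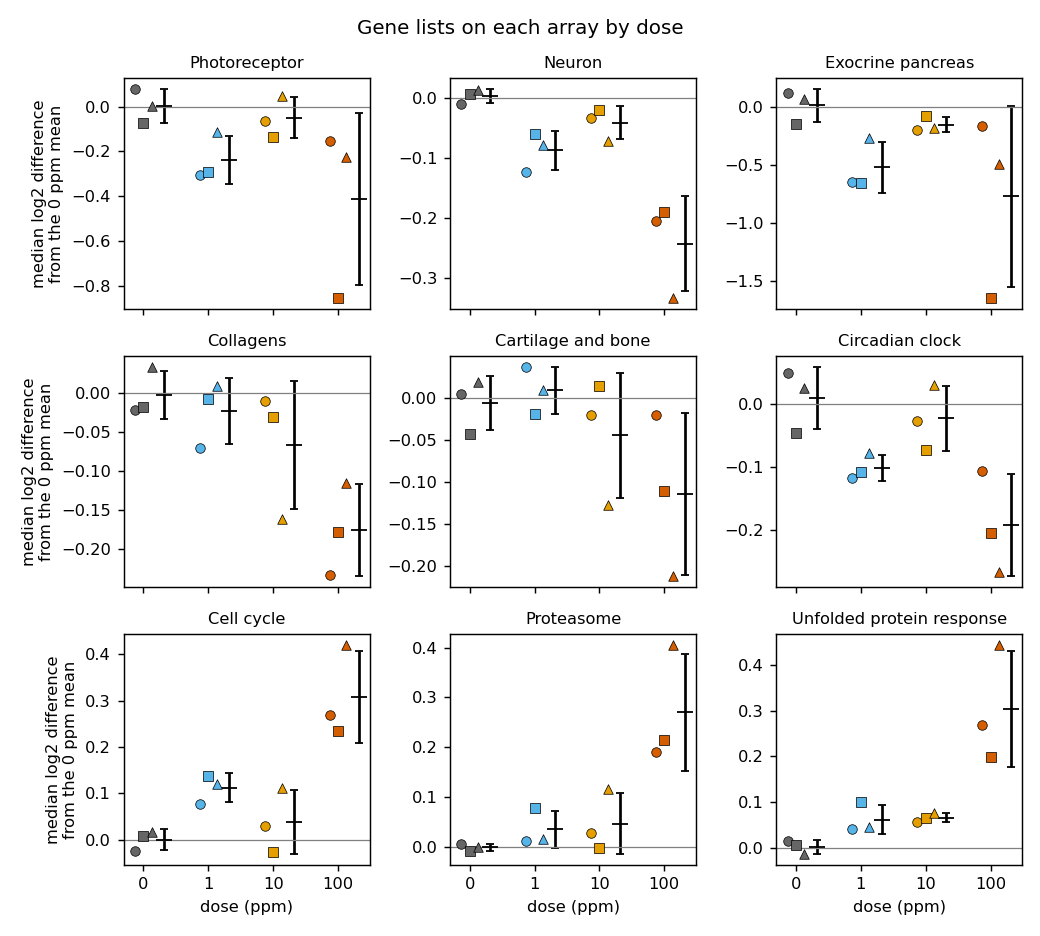
Median over the genes of 9 lists of the log2 difference from the 0 ppm mean, per array and dose, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean ± SD of 3 arrays. The neuron list was lower on all 3 arrays at 100 ppm; photoreceptor and exocrine pancreas genes were lowest on 100 ppm replicate 2, and proteasome and unfolded protein response genes highest on 100 ppm replicate 3.

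At 10 ppm no gene passed limma's test. The genes with the lowest p were zgc:194114 (1.12 ± 0.17; well above background on 1 of 3 arrays at 0 ppm), si:ch211-282j17.11 (-1.42 ± 0.25), the calcium channel gene cacna1ba (0.66 ± 0.13), kiaa1109 (-0.57 ± 0.11) and the immediate early gene fosab (0.63 ± 0.13). The lowest adjusted p was 0.579, and without 100 ppm replicate 3 a single gene passed (1 of those tested). At an unadjusted p below 0.05, 279 genes differed, fewer than the 649.9 that chance alone would give. The fit shares its spread with the wider 100 ppm arrays and has no slide block, so it can be too strict here. The count is then no measure of how little changed, and with array weights some genes passed. The same limit holds at 1 ppm and between 10 and 1 ppm. The exposure markers differed by -0.03 for cyp1a, 0.05 for cyp1b1, 0.06 for cyp1c1, -0.03 for ahrra, -0.14 for hmox1a, 0.14 for mt2 and 0.16 for hsp70l. Of these signs, some turned under other settings: that of cyp1b1 and cyp1c1 with the mean of probes, that of ahrra with quantile normalization, and those of cyp1a, cyp1b1, ahrra and hmox1a without single arrays.

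In the list test 13 of 42 lists shifted at 10 ppm with the preset correlation and none with an estimated one; 11 held with slide as a block and none passed fry. No member of any list passed, also adjusted over the list alone. Shifts were small: the largest were those of exocrine pancreas (-0.20 relative to all genes; 16 of 18 lower; adjusted p = 0.00166; adjusted p = 0.693 with an estimated correlation), collagens (-0.11; 14 of 18 lower; adjusted p = 0.000298; adjusted p = 0.103 with an estimated correlation) and complement (-0.11; 17 of 21 lower; adjusted p = 0.00107; adjusted p = 0.385 with an estimated correlation). Genes of neurons, photoreceptors, intestine, clock, sterol synthesis, drug metabolism, matrix, and cartilage and bone were lower too, and those of oxidative phosphorylation (0.04; 52 of 64 higher) and of yolk and egg (0.08; 15 of 19 higher) were higher. Matrix (adjusted p = 0.0529) and cartilage and bone (adjusted p = 0.0529) did not pass with slide as a block. The count of shifted lists was 7 and 8 without 0 ppm replicate 1 and 3, and 5 without 10 ppm replicate 2.

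The 2 members of each list with the lowest p at 10 ppm, none of which passed, had these differences. In connective tissue lists they were col9a1b (-0.66), col8a1a (-0.34), has2 (-0.31), fbln1 (-0.36) and hapln1a (-0.22). In blood and immune lists they were rhag (-0.22), gata1a (0.36), rac2 (0.20), fcer1gl (0.23), mpl (-0.88), itga2b (0.33), tek (0.30), dll4 (-0.18), c8b (-0.29), c3a.2 (-0.22), ptgs2b (0.47), nfkbiaa (0.33), irf1a (0.56) and socs1a (0.23). In muscle lists they were jph1b (0.24), actn3b (0.18), cmlc1 (0.15), has2 again, mef2d (-0.58) and pax3a (-0.30). In digestive lists they were tdo2b (-0.53), vtnb (-0.19), cel.1 (-0.64), ela2l (-0.69), alpi.2 (-0.68), slc15a1b (-0.44), he1.1 (1.17) and zp3b (0.24). In nerve and sense organ lists they were grk7b (-0.22), elovl4b (0.15), crygm4 (0.44), grifin (0.22), slc32a1 (-0.48), slc17a7a (-0.49), her4.1 (0.19), plp1b (-0.29), s100t (0.18) and pvalb9 (0.13). In stress and exposure lists they were tiparp (-0.19), cyp1c2 (0.17), nfe2l2a (-0.25), txnb (0.16), nr1i2 (-0.47), cyp2aa4 (0.28), slc39a10 (-0.19), hsp70.3 (0.18), serpinh1b (0.48), dnajb1a (0.21), dnajc3a (0.19), sdf2l1 (0.15), xpc (-0.31), btg2 (0.35), ero1a (0.26), epoa (-0.41), socs3a (0.58) and anxa1c (0.28). In the lists of metabolism, clock and cell growth they were bmal1b (-0.21), cry5 (-0.34), cyp51 (-0.27), insig1 (-0.39), elovl2 (-0.39), scdb (-0.41), mcm5 (0.14), cks1b (0.19), rpl29 (0.21), rpl34 (0.12), ndufa1 (0.27), uqcrb (0.17), psmd4a (0.18) and psmc4 (0.13). In the lists of skin, ion transport, pigment and hormones they were krt97 (0.24), krt18b (0.18), atp1a1a.3 (-0.28), stc1l (-0.32), kita (0.34), trpm1b (0.23), smtlb (-0.44) and sst1.1 (0.19).

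At 1 ppm no gene passed limma's test either. The genes with the lowest p were pth1a (0.96 ± 0.18), which also rose at 100 ppm, lepa, which encodes leptin (0.87 ± 0.17), zgc:174917 (1.25 ± 0.25), si:dkey-83f18.9 (0.93 ± 0.19) and fosab (0.63 ± 0.13). The lowest adjusted p was 1.00, and 345 genes differed at an unadjusted p below 0.05, against 649.9 by chance. Among the exposure markers ahrra differed by -0.45 ± 0.10 (unadjusted p = 0.00069), cyp1a by -0.30, cyp1b1 by 0.08, cyp1c1 by 0.07, hmox1a by -0.10, mt2 by -0.11 and hsp70l by 0.20. The sign of cyp1b1 turned with the mean of its probes and without 1 ppm replicate 2.

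In the list test 15 of 42 lists shifted at 1 ppm with the preset correlation and none with an estimated one; 14 held with slide as a block and none passed fry. All 42 cell cycle genes were higher (0.08 relative to all genes; adjusted p = 1.0e-06; adjusted p = 0.249 with an estimated correlation). Photoreceptor genes were lower, 41 of 47 (-0.27; adjusted p = 2.6e-13; adjusted p = 0.249 with an estimated correlation), with medians of -0.39, -0.18 and -0.12 on the 3 slides. Exocrine pancreas genes were lower, 16 of 18 (-0.58; adjusted p = 2.0e-10; adjusted p = 0.249 with an estimated correlation), and so were liver genes, 29 of 38 (-0.13; adjusted p = 7.2e-07; adjusted p = 0.249 with an estimated correlation). Of the blood and immune lists, 4 were higher: erythroid genes by 0.07 (30 of 36; adjusted p = 1.3e-05; adjusted p = 0.181 with an estimated correlation), inflammation genes by 0.14, myeloid genes by 0.09 and interferon genes by 0.14. The complement (-0.09), thrombocyte (-0.03) and blood vessel (0.03) lists did not pass. The unfolded protein response was higher as well (0.05), though not with slide as a block (adjusted p = 0.0528). Neuron, intestine, clock, drug metabolism, sterol and lipid lists were lower. No gene passed over all genes; adjusted over the list alone, 3 erythroid genes, 1 lens gene and 1 gene of the aryl hydrocarbon receptor list did.

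The members of each list with the lowest p at 1 ppm, at most 2 per list, had these differences. In blood and immune lists they were alas2 (0.51), klf1 (0.45), ncf1 (0.53), fcer1gl (0.32), f7 (-0.31), f13a1b (0.21), sox7 (0.23), tek (0.21), cfb (0.31), crp2 (-0.34), socs3a (0.74), tnfb (0.72), mxe (0.29) and irf1a (0.61). In connective tissue lists they were col5a3a (-0.17), col9a1b (-0.26), fn1b (0.28), p4ha1b (0.44), matn3b (-0.49) and mgp (0.24). In muscle lists they were jph1b (0.29), pvalb8 (-0.19), has2 (-0.14), tnni1b (0.17), meox1 (0.19) and mef2d (-0.55). In digestive lists they were tdo2b (-0.63), rbp4l (-0.38), cpa1 (-0.63), prss1 (-0.44), slc15a1b (-0.77), chia.3 (-0.63), he1.1 (1.28) and ctslb (0.94). In nerve and sense organ lists they were rbp4l again, grk7b (-0.27), crygm7 (0.78), crygm4 (0.35), cplx4c (-0.39), slc17a7a (-0.42), her4.1 (0.20), plp1b (-0.25), oc90 (0.47) and cdh23 (-0.54). In stress and exposure lists they were ahrra, foxq1b (0.34), abcc2 (-0.26), gsta.1 (-0.19), nr1i2 (-0.40), ugt5b1 (-0.44), hsp70.3 (0.22), hsp70l, serpinh1b (0.40), hspa1b (0.29), atf3 (0.39), sesn2 (0.19), xpc (-0.34), gadd45bb (0.24), bnip3la (-0.33), ero1a (0.30), socs3a and tsc22d3 (-0.25). In the lists of metabolism, clock and cell growth they were nr1d1 (-0.39), per2 (-0.44), insig1 (-0.34), sc5d (-0.23), elovl2 (-0.31), acox3 (-0.24), mcm5 (0.23), mcm3 (0.20), rpl29 (0.13), rpl8 (0.17), cox6b1 (0.15), ndufa1 (0.14), psme3 (0.16) and psmc4 (0.11). In the lists of skin, ion transport, pigment and hormones they were krt1-c5 (-0.24), apoda.2 (-0.36), atp1a1a.3 (-0.20), trpm1b (0.31), mitfa (0.30), cyp17a1 (0.38) and dio2 (0.25).

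Differences between the doses themselves were tested with the same model, which answers whether the response depends on dose. Between 100 and 10 ppm, smtlb was lower at 100 ppm by -1.54 ± 0.13 (adjusted p = 0.00135) and fabp4b higher by 1.57 ± 0.16 (adjusted p = 0.00568). kctd16b was lower at 100 ppm (adjusted p = 0.0462), where it was not well above background. Between 100 and 1 ppm the same 3 genes differed, smtlb by -1.76 ± 0.13, fabp4b by 1.21 ± 0.16 and kctd16b with an adjusted p of 0.0449, together with anxa1b (-0.88 ± 0.11; adjusted p = 0.0373). These were 3 and 4 of 12998 genes; with slide as a block 5 and 6 passed. At an unadjusted p below 0.05, 3237 and 2838 genes differed, where the shared spread can again be too narrow for the 100 ppm arrays. Without 100 ppm replicate 1, 2 and 3 the counts were 46, 2417 and 17 against 10 ppm and 9, 2076 and 4 against 1 ppm. Without any array of 0, 1 or 10 ppm they lay between 1 and 3.

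Between 10 and 1 ppm 11 genes differed, and all were lower at 10 ppm. One of them, cyp26a1, encodes the enzyme that degrades retinoic acid; it stood at 3.17 ± 0.38 (SD, n = 3) at 1 ppm, and the difference was -1.13 ± 0.17 (adjusted p = 0.0471; slides -1.19, -1.55 and -0.66). The other 10 have provisional names and differed by -1.42 for si:dkey-88n24.6 up to -2.11 for si:ch211-282j17.11. The gene table places 6 of them (si:ch211-282j17.3, si:ch211-282j17.11 and si:dkey-88n24.6, si:dkey-88n24.7, si:dkey-88n24.8 and si:dkey-88n24.9) in a run of neighbouring genes, and the remaining 4 (si:dkey-83f18.2, si:dkey-83f18.9, zgc:162060 and si:ch211-225k7.6) in another. Against 0 ppm these 10 genes were between 0.69 and 1.05 higher at 1 ppm and between -1.42 and -0.61 lower at 10 ppm, with none passing the test there. All 6 measured genes of the first run differed by less than -1, as did 5 of 7 in the other. There si:dkey-83f18.5 (0.16) and si:dkey-83f18.7 (-0.67) did not. These neighbours may be similar copies that probes share, which was not checked by sequence, so each single gene is uncertain. With slide as a block 10 of the 11 passed, and without any 1 of the 3 arrays at 10 ppm none did. At an unadjusted p below 0.05, 149 genes differed between 10 and 1 ppm, against 649.9 by chance, with the limit of the shared spread named above.

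**Figure D4:**
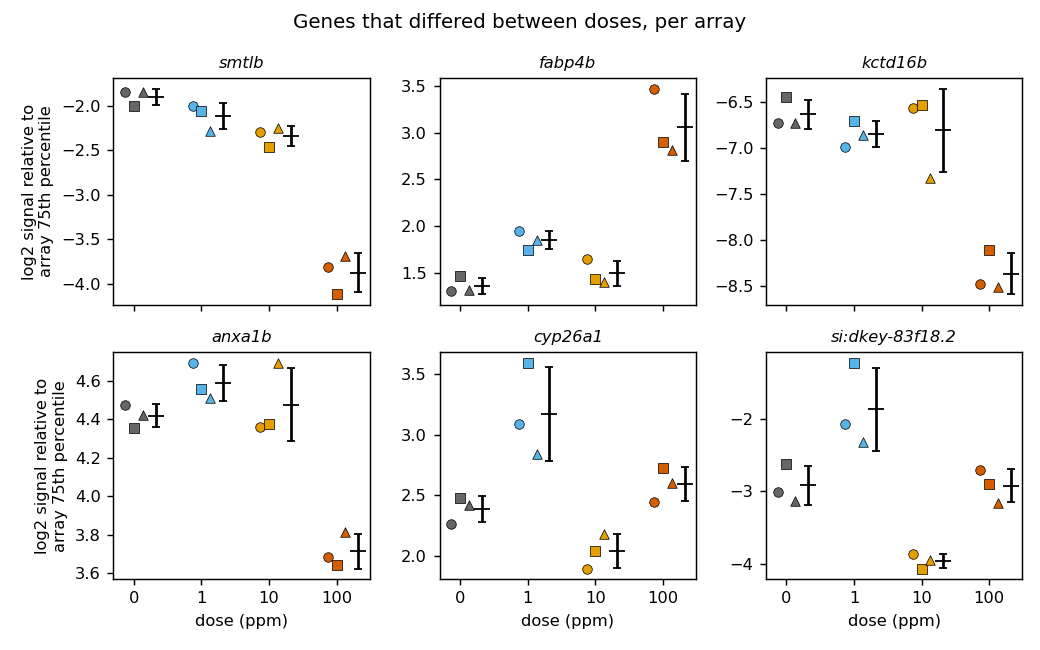
Log2 signal relative to the array's 75th percentile of 6 genes that differed between 2 doses, per array, with circles, squares and triangles for replicates 1, 2 and 3 and black bars for the mean ± SD of 3 arrays. smtlb, kctd16b and anxa1b were lowest and fabp4b highest at 100 ppm, while cyp26a1 and si:dkey-83f18.2 were highest at 1 ppm and lowest at 10 ppm. kctd16b was not well above background on any array at 100 ppm.

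A trend over log10(dose + 1) was found in 913 genes, 592 rising and 321 falling, of which 720 had passed at 100 ppm. The balance turned with the mean of a gene's probes (167 rising and 270 falling), with array weights (44 and 81) and with an unadjusted p below 0.05 and a change of 1.5-fold (240 and 777). Beyond the genes already named, the steepest rises per unit of log10 dose were those of snapc1a (0.55), ocstamp (0.53), tsnaxip1 (0.45), ccnb1l, a cyclin B gene (0.42), and ovol1a (0.41). The steepest falls were those of pcsk2, a prohormone convertase (-0.73), the axon guidance gene sema3aa (-0.65), the integrin gene itgb1b.1 (-0.65), aspa (-0.64) and stxbp1b, a syntaxin binding protein of synapses (-0.63). With the rank of the dose in place of its logarithm no gene passed, and with slide as a block 1983 did. The count was 3, 2 and 2 without 0 ppm replicate 1, 2 and 3, 7, 359 and 2 without those of 1 ppm, 58, 1746 and 259 without those of 10 ppm, and 42, 2980 and 512 without those of 100 ppm. More genes fell than rose without replicate 1 of 1 ppm (2 rising and 5 falling), 10 ppm (20 and 38) or 100 ppm (13 and 29), and none rose without any single 0 ppm array or 1 ppm replicate 3. A test over all 3 doses at once passed for smtlb and fabp4b only; it passed 34, 714 and 69 genes without 100 ppm replicate 1, 2 and 3, 10 without 1 ppm replicate 2, 4 without 10 ppm replicate 3 and 1 without 0 ppm replicate 1 or 3.

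The doses share their 0 ppm arrays, so differences from 0 ppm would correlate between doses even if no dose had an effect. Across genes, log2 differences correlated with r of 0.49 between 100 and 10 ppm, 0.57 between 100 and 1 ppm and 0.59 between 10 and 1 ppm (Spearman's rho 0.49, 0.62 and 0.63; genes are not independent replicates). Unchanged groups simulated against a shared, simulated 0 ppm group gave 0.50 for each. The covariance was 0.0285, 0.0380 and 0.0146 against simulated values of 0.0183, 0.0183 and 0.0183. The differences were 0.0103, 0.0197 and -0.0037. The simulation drew the 0 ppm values anew with 1 spread per gene for all doses, and its groups did not share slides as the arrays do. Its r of 0.50 follows from that design. Its covariance can be too high, since the wider 100 ppm arrays enter the spread. These differences therefore do not settle how much of the correlation comes from the controls.

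The authors' deposited table for 100 ppm lists 4933 probes with a fold change of at least 1.5, of which 1887 are higher and 3046 lower. The authors' deposited tables list 567 probes at 10 ppm and 573 at 1 ppm. Of those at 100 ppm, 4282 were tested here as single probes. Each had the same sign, 4268 had an unadjusted p below 0.05 by limma, and 5 passed after adjustment over 89578 probes. The tables come from these same arrays, so the shared sign is not separate support. Here 11874 probes had an unadjusted p below 0.05 and a change of 1.5-fold at 100 ppm, of which 3676 are listed. Of the largest rises and falls named above, tyro3 and syt10 have no listed probe and each other gene has at least 1. Of those at 10 ppm 236 were tested, with 185 at an unadjusted p below 0.05 and 0 passing, and of those at 1 ppm 287, with 229 and 0. The log2 fold changes computed here followed those of the authors' deposited tables with an r of 1.00. Those here were lower by a constant, with a difference of -0.08 at 100 ppm, -0.019 at 10 ppm and -0.017 at 1 ppm. The lists of the authors' deposited tables overlapped by 345 probes between 100 and 10 ppm, 390 between 100 and 1 ppm and 265 between 10 and 1 ppm, of which 306, 368 and 231 had the same direction. Independent lists of these sizes would share 10.73, 11.48 and 1.38 in the same direction, a figure that leaves out the shared controls; 179 probes were in all 3 lists.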

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

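The test of every kept probe was planned, while the choice to read the probes without a matched gene was made only after the result was seen. When each of 89578 kept probes was tested by itself, 5 passed at 100 ppm, and 2 of these belong to no gene of the tests above. Per the authors' description, one reads a transcript like human chromosome 1 open reading frame 51, known as CIART, a repressor in the circadian clock. Its log2 change was -1.20 ± 0.13 (SE; adjusted p = 0.0398 by limma), from -0.28 ± 0.16 (SD, n = 3) at 0 ppm, and -1.06, -1.12 and -1.41 on the 3 slides. The other, described as solute carrier family 24 member 2, a sodium, potassium and calcium exchanger, changed by -1.50 ± 0.16 (SE; adjusted p = 0.0398 by limma), from -1.93 ± 0.15 (SD, n = 3), and by -1.17, -1.71 and -1.64 on the slides. Both were well above background on all 3 arrays of both doses. The match of these probes to zebrafish genes rests on the description alone, and no explanation was tested.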

How the results depend on the processing

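Leaving out 100 ppm replicate 3 together with a replicate block was chosen only after the result was seen; all other alternatives here were planned. The counts of shifted lists at 100 ppm were between 8 and 14 in all alternatives except camera with an estimated correlation, and no gene passed at 10 or 1 ppm except as stated here. Where no cause is given, the cause was not tested.

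With the replicate block, which is also the slide block, 2056 genes changed at 100 ppm against 988, all 988 among them; 5 differed between 100 and 10 ppm, 5 at any dose and 1983 along the trend. With only the groups compared in the fit, the spread came from those arrays alone. Then 0 genes changed at 100 ppm, 0 between 100 and 10 ppm, 0 between 100 and 1 ppm, 0 between 10 and 1 ppm and 0 along a trend over 0, 1 and 10 ppm. With 100 ppm replicate 3 left out and a replicate block, 3142 genes changed at 100 ppm (967 of the 988 among them) and 1 at 10 ppm, 8 lists shifted at 10 ppm, and 396, 26 and 3 genes differed between 100 and 10, 100 and 1, and 10 and 1 ppm.

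Normexp background gave 2102 genes at 100 ppm, 40 at any dose and 2067 along the trend; the correlation of changes was 0.572 between 100 and 10 ppm and 0.645 between 10 and 1 ppm, and 98.3% of the probes listed by the authors at 1 ppm had the same sign. Quantile normalization gave 10 genes between 100 and 10 ppm and 35 at any dose, and ahrra was 0.129 at 100 ppm and 0.000345 at 10 ppm. Scaling by the median of probes well above background gave 1782 genes at 100 ppm and 2169 along the trend, with ahrra at 0.0418 at 100 ppm; the median of all genes moved from 0.11 to 0.19. Without a filter 2 genes differed between 100 and 1 ppm.

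The mean of a gene's probes gave 16 genes at any dose and 437 along the trend, and turned the sign of cyp1b1 (-0.307), ahrra (0.0539), atp2a1l (-0.0519) and unc45b (-0.0212) at 100 ppm, of cyp1b1 (-0.144) and cyp1c1 (-0.0789) at 10 ppm and of cyp1b1 (-0.0177) at 1 ppm. At 100 ppm 712 genes passed (301 higher and 411 lower), of which 456 were among the 988. Testing every kept probe, where more tests are adjusted for, gave 3 genes at 100 ppm, 1 between 100 and 10 ppm, 1 between 100 and 1 ppm, 0 between 10 and 1 ppm, 1 at any dose and 0 along the trend.

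eBayes with trend and robust gave 1506 genes at 100 ppm, 8 at any dose and 1641 along the trend. Array weights gave 4032 genes at 100 ppm, 21 at 10 ppm, 3 at 1 ppm, 2940 between 100 and 10 ppm, 2636 between 100 and 1 ppm, 76 between 10 and 1 ppm, 3170 at any dose and 125 along the trend. An unadjusted p below 0.05 with 1.5-fold gave 38 genes at 10 ppm, 86 at 1 ppm, 842, 658 and 39 between 100 and 10, 100 and 1, and 10 and 1 ppm, and 877 at any dose. An adjusted p below 0.1, a looser threshold, gave 3634 genes at 100 ppm, 16 between 100 and 10 ppm, 8 between 100 and 1 ppm, 55 at any dose and 3890 along the trend. The rank of the dose gave 0 genes along the trend. Camera with an estimated correlation shifted 1, 0 and 0 lists at 100, 10 and 1 ppm, and fry shifted 0 at 10 ppm and 0 at 1 ppm.

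Leaving out single arrays or all arrays of a replicate number gave 0 to 4251 genes at 100 ppm, 0 to 1 at 10 ppm, 0 to 2417 between 100 and 10 ppm, 0 to 2076 between 100 and 1 ppm, 0 to 11 between 10 and 1 ppm, 0 to 714 at any dose and 0 to 2980 along the trend. It gave 8 to 14 lists at 100 ppm, 5 to 19 at 10 ppm and 13 to 17 at 1 ppm. At 10 ppm cyp1a turned to 0.0598 without 0 ppm replicate 2, 0.0162 without 10 ppm replicate 2 and 0.108 without replicate 2 (range -0.141 to 0.108). cyp1b1 turned to -0.0752, -0.0300 and -0.0305 without 10 ppm replicate 2, 0 ppm replicate 3 and replicate 2 at 10 ppm (range -0.0752 to 0.142), and to -0.0158 without 1 ppm replicate 2 at 1 ppm (range -0.0158 to 0.172). ahrra turned to 0.00734 without 10 ppm replicate 2 and 0.00321 without 0 ppm replicate 3 at 10 ppm (range -0.0656 to 0.00734), and to 0.0115 without 100 ppm replicate 2 at 100 ppm (range -0.0843 to 0.0115). hmox1a turned to 0.0293 without 10 ppm replicate 2 and 0.0155 without replicate 2 at 10 ppm (range -0.253 to 0.0293). None of these genes had passed at those doses.

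Of the named genes that passed at 100 ppm, none still passed with only the groups compared; 100 were lost without any 1 of the 0 ppm arrays, 40 with the mean of probes, 22 without a filter and 8 without 100 ppm replicate 3, and none was lost with the block, the deposited values or without 100 ppm replicate 2. Signal over background limits kctd16b and cacng7a, whose levels at 100 ppm are not known.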

Other observations

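The tests of 100 ppm replicate 3 as a stronger form of the change and as the only source of the calls, and those leaving out single arrays for 4 lists, were chosen only after the result was seen; the lists of retinoic acid and progenitor genes were written after the gene tests. At 100 ppm 25 of 37 genes of the retinoic acid list were higher and 12 lower. The list holds receptors, enzymes and binding proteins of the pathway besides hox genes, so a change is not by itself a response to retinoic acid. By the gene test 6 rose, stra6 (0.86), rbp5 (0.79), hoxb5b (0.75), hoxa5a (0.74), hoxb6b (0.54) and hoxb1b (0.50), and 2 fell, rxraa (-1.38) and rarga (-0.59); the falls of rargb (-1.28) and rxrab (-1.08) did not pass. The list had a median of 0.10 relative to all genes and lay at percentile 89.1 among 10000 random lists of matched level, within their middle range. At 1 ppm its median was 0.07, at percentile 99.95 (29 of 37 higher), and at 10 ppm -0.02, at percentile 11.4.

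Other splits of the same arrays were tested for each count. For comparisons of 3 with 3 arrays there are 10 splits, too few for a share under 0.05. The real split is counted among those as large. The real split gave 988 genes at 100 ppm and the highest other 0, with 1 split as large; at 10 and at 1 ppm the real and the highest other gave 0, so all 10 were as large. Between 100 and 10 ppm the values were 3 and 1, between 100 and 1 ppm 4 and 0, and between 10 and 1 ppm 11 and 0, each with 1 split as large. For lists they were 11 and 17 at 100 ppm (2 splits as large), 13 and 10 at 10 ppm (1 split) and 15 and 11 at 1 ppm (1 split). Of 100 splits of the 12 arrays, only the real one gave as many genes along the trend as its 913 (highest other 4), a share under 0.05. At any dose 4 of the 100, the real one among them, gave as many as the real 2. That is also a share under 0.05, though the highest other gave 3, more than the real split. The splits did not keep slides together, so neither share excludes chance for this design. Nor can the split test tell a trend from a difference at 100 ppm alone, and no gene passed with the rank of the dose.

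The array of 100 ppm replicate 3 stood apart from the other 11. It is not the only source of the calls at 100 ppm, since 900 of the 988 genes also passed without it. Probes of the same gene drifted apart on it by 1.73 times the highest of the other arrays, as partly degraded RNA or uneven labelling would give. Divided by the spread between genes, which rose as well, the drift was 0.817 on it and 0.672 to 1.15 on the others, so it does not set this array apart. Of 1698 genes called without it, 85.6% went the same way on it against the 1 and 10 ppm arrays of its slide (67.8% of all genes did), with a median ratio of 1.32, so a stronger form of the same change may add to it. Both explanations stay open.

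Neighbouring genes and cyp26a1 were lower at 10 than at 1 ppm. Deviations of the 10 called neighbours from their dose means correlated with a median r of 0.860 (highest of 1000 random gene sets 0.687), which may reflect probes that read several similar copies; shared regulation would give the same. A difference in retinoic acid signalling is a further hypothesis: the list without cyp26a1 had a median of -0.0784 relative to all genes (32 of 37 lower; camera p = 1.6e-11, and 0.00015 with an estimated correlation), with dhrs3a at -0.80 and cyp26c1 at -0.67. It lay at percentile 0 among 10000 random lists (middle range -0.03 to 0.03), but its size stayed short of the bound of -0.1 set before the list was tested. The list was written after cyp26a1 had been called in this same comparison, so these values are not independent support. The test leaves the hypothesis open.

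At 100 ppm the photoreceptor, neuron and exocrine pancreas lists were lower and cell cycle genes higher, of which the neuron list alone held with an estimated correlation, and photoreceptor and exocrine pancreas did not pass fry; cardiac muscle (0.19), pigment (0.20) and erythroid (0.04) lists had medians above that of all genes. Leaving out 100 ppm replicate 2 moved the photoreceptor median by a factor of 1.74 and that of exocrine pancreas by 1.66, so that array sets much of their size, though both lists still passed. The neuron and cell cycle medians moved by at most 1.25 and 1.21 whichever 100 ppm array was left out, which argues against 1 array at 100 ppm as their source. Arrays of the other doses were not left out in this test. Delayed development may also play a part: 38 progenitor genes had a median of 0.0283 relative to all genes (percentile 37.1 among 10000 random lists), which decides neither way, with 27 higher and 11 lower. Of these sox19a (0.63), sox2 (0.53), ascl1a (0.37) and insm1a (0.35) passed the gene test, while the falls of notch1b (-0.99), notch3 (-0.90) and pax6b (-0.59) did not. A change in the makeup of the larva was not tested apart from these lists.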
